A study of Arabidopsis thaliana with 4 samples.

How the data were processed

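Expression profiles of Arabidopsis thaliana shoot apices were analysed, 2 arrays from plants incubated with dexamethasone and 2 from plants incubated without it. The plants were Ws-0 seedlings that carry LEC1 fused to the glucocorticoid receptor domain (GR) under the 35S promoter. Per the labels' protocols, seedlings aged 8 days were kept for 1 h in liquid medium with or without 30 µM dexamethasone, and shoot apices were then dissected and frozen. Total RNA was turned into biotin-labelled cRNA, per the labels' protocols. The control probe sets carry Arabidopsis names of the Affymetrix type.

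The authors deposited one log2 expression value per probe set and array. Per the submitters' processing notes the values came from RMA and the affy package. Their versions, any filter and any quality check of the arrays are not given in the sources used here. The log2 scale follows from RMA and from the values, whose medians lay between 6.56 and 6.61 in the 4 arrays. RMA sets arrays to a common distribution and pools the probes of a probe set, so a shift shared by all transcripts could not be seen. No detection call was used. As a control level, the highest of 27 probe sets for Bacillus control transcripts was taken in each array, 4.68 to 4.86. Whether those transcripts were added to the samples is not given in the sources used here. A fold given as at least a value sets every array at or below that level to it. This floor was added after the data were seen. Array signals carry no read depth, and the number of arrays limits the precision.

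The table held 22810 probe sets. The 64 control probe sets were left out, and 22746 were tested. Genes were named through the platform annotation's gene identifiers, matched to the reference gene table for current symbols. Of the tested probe sets, 13513 matched 1 gene, 503 matched several and 8730 were unnamed here. Of the 13513, 13436 were found in the reference gene table, and 11885 have only a locus code as a symbol. No gene was named from a probe set that matched several. A gene with more than 1 probe set was represented by the one with the highest mean, which gave 13356 genes. Among 146 genes with several probe sets, 2 had one called probe set and another that was uncalled or opposite. No chromosome coordinates are printed, because no genome build is named for these values.

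Groups and replicate numbers were taken from the sample titles, and the series design text calls the replicates biological. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 22746 probe sets and an adjusted p threshold of 0.05. The fit used no block, trend or filter. Its prior degrees of freedom were 3.09, so the tests rested largely on a spread pooled across probe sets. Differences are dexamethasone minus none on the log2 scale, errors of means are SDs of 2 arrays, and errors of differences are limma's standard errors.

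Before the data were examined, 21 gene lists with 271 genes were fixed for seed maturation, hormones, photosynthesis, stress, the clock and cell types. Only 32 of these genes had a probe set that matched 1 gene. Lists with at least 3 measured genes were tested with camera, at a preset correlation between genes of 0.01 and again at an estimated one. The rule for named genes was fixed then too. It took the 15 largest rises and 15 largest falls among called probe sets that match 1 gene and whose arrays do not overlap between groups. From each list it took up to 4 called members, or the 2 with the smallest p where none was called. LEC1, NF-YB6, LEC2, FUS3 and ABI3 were to be named always. They are unnamed here, so the check of the targeted gene could not be made. The planned test of promoter motifs in 500 bp or 1000 bp upstream was not run, because no genome sequence was used here.

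Families of at least 5 genes that share the letters at the start of their symbols were added after the annotation was seen to name few list genes. The 3 further lists, of carbon-starvation, wound and root genes, were written after the calls were seen. The alternatives covered a replicate block, dim probe sets left out, 2 further scalings, trend and robust eBayes, an unmoderated test, probe sets that match 1 gene, a 2-fold minimum, an adjusted p of 0.01 and leaving out each array in turn.

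The fit was tested on simulated data with 2 arrays per group, 22746 probe sets and 200 of them changed. It recovered 11.5% of the 2-fold changes, 79.1% of the 4-fold changes and 95.8% of the 8-fold changes. Of the 144 simulated calls, 15 were not changed. Most 2-fold changes were thus missed when 200 probe sets were changed. The share found depends on how many are changed. With 2000 changed probe sets the fit made 1902 calls, which were not split by size of change. Both simulations drew an equal spread for the 2 groups, unlike the data.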

Results

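Transcript levels were measured on 4 arrays of shoot apices dissected from Arabidopsis thaliana seedlings aged 8 days. All plants were Ws-0 carrying 35S:LEC1-GR. LEC1 is an NF-Y B subunit that controls embryo development and seed maturation, and the GR domain keeps the fusion protein inactive until dexamethasone is added. Seedlings were incubated for 1 h in liquid medium with 30 µM dexamethasone (2 arrays) or without it (2 arrays). The values are log2 RMA expression values as deposited, one per probe set. The control level in each array is the highest value among its Bacillus control probe sets, 4.68 to 4.86. No depth applies to array signals, and the 2 arrays per group limit the precision. The arrays correlated across probe sets at 0.983 within the untreated group, at 0.992 within the dexamethasone group and at 0.969 to 0.979 between groups.

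The comparison asked which transcripts differed after 1 h of LEC1-GR induction. COR27, a cold-regulated and clock-regulated gene, fell from 8.75 ± 0.24 to 4.81 ± 0.01 (SD, n = 2 per group), which is 15.4-fold lower. Its dexamethasone values lay barely above the control level of their arrays, so the size of that fold is uncertain. HYH, a bZIP factor of light signalling related to HY5, rose from 4.59 ± 0.80 to 8.31 ± 0.14, at least 9.87-fold when its 1 dim untreated array is set to the control level. WRKY22, an immune transcription factor, rose 5.48-fold, and the expansin gene EXPA8 fell 5.19-fold. The gibberellin receptor genes went in opposite directions, with GID1A falling 2.899-fold and GID1B rising 2.289-fold. The auxin-response gene IAA29 fell 3.43-fold.

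In limma with Benjamini-Hochberg adjustment, 339 probe sets were higher and 200 lower with dexamethasone, 2.37% of the 22746 tested. Of these, 166 of the higher and 94 of the lower probe sets matched 1 gene. The median fold was 2.57 for the higher and 2.47 for the lower probe sets, and 295 and 162 of them differed at least 2-fold. In all 539 called probe sets both dexamethasone arrays lay on the same side of both untreated arrays. That separation was seen in 47.2% of all tested probe sets, against 33.3% by chance. The lowest limma adjusted p was 0.0173, and 3902 probe sets had an unadjusted p below 0.05. The median difference over all probe sets was -0.017.

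**Figure D1:**
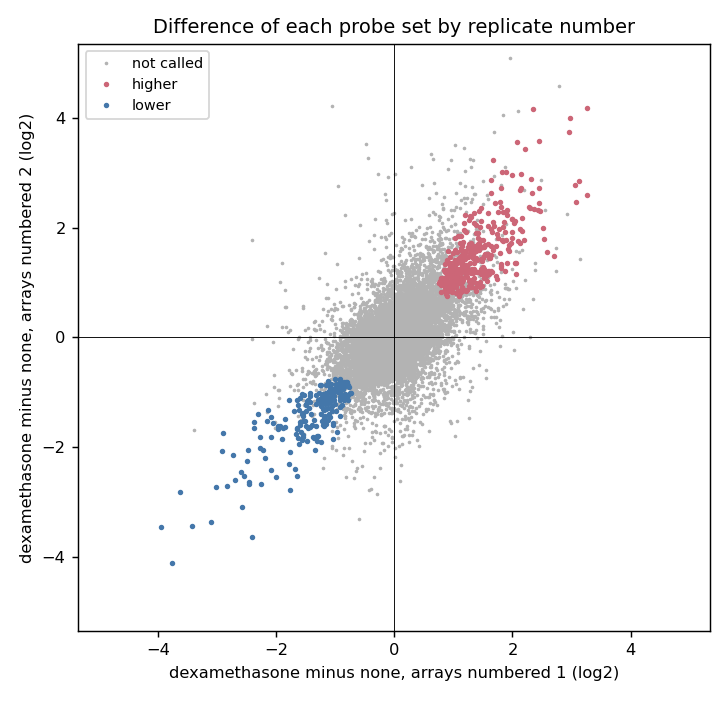
Difference between dexamethasone and no dexamethasone (log2) for each tested probe set, from the arrays numbered 1 on the horizontal axis and those numbered 2 on the vertical axis. The 339 probe sets called higher (red) lie above 0 on both axes and the 200 called lower (blue) below 0 on both, while grey points were not called.

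Among the largest rises, HYH changed by 3.72 ± 0.38 (log2 difference ± SE, limma adjusted p = 0.0301). AT1G22810, an ERF/AP2 transcription factor gene, rose by 3.36 ± 0.21 (limma adjusted p = 0.0228). The leucine-rich repeat receptor kinase gene AT1G51820 rose by 2.93 ± 0.27, at least 4.65-fold because both untreated arrays lay at or below the control level, and the lectin receptor kinase gene B120 rose by 2.17 ± 0.28, at least 4.17-fold with 1 dim untreated array. WRKY22 rose by 2.46 ± 0.23 and the VQ-motif gene AT2G22880 by 2.09 ± 0.32. AT3G44450, which is BIC2, an inhibitor of cryptochromes, rose by 2.43 ± 0.18. AT4G22470, of the lipid-transfer protein type, rose by 2.26 ± 0.18, and the oxygenase gene AT2G36690 by 2.097 ± 0.31. AT1G65490 (2.82), AT2G21510 (2.48), AT2G16900 (2.26), AT2G19650 (2.12), AT1G56660 (2.08) and AT1G56060 (2.07) completed the 15 largest rises. The limma adjusted p of these 15 genes ranged from 0.0228 to 0.0498, and that of AT2G36690 was 0.0513 without untreated replicate 2.

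Among the largest falls, COR27 changed by -3.95 ± 0.16 (log2 difference ± SE, limma adjusted p = 0.0173). AT4G33980, which is COR28, its close relative, fell by 3.24 ± 0.14 (limma adjusted p = 0.0173). AT1G07050, a CCT-domain gene, fell by 3.71 ± 0.18, at least 7.27-fold because both dexamethasone arrays lay at or below the control level. AT2G20670 and AT2G38820, of the DUF506 family, fell by 3.23 ± 0.23 and by 1.96 ± 0.24. AT3G15450 fell by 2.54 ± 0.14, from 13.10 ± 0.10 to 10.55 ± 0.12. The kelch F-box gene AT1G23390, whose product targets chalcone synthase, fell by 2.502 ± 0.22. EXPA8 fell by 2.38 ± 0.17 and P1R3 fell by 2.05 ± 0.18, at least 3.44-fold for the same reason as AT1G07050. AT4G14270 (-2.77), AT3G15630 (-2.57), AT3G26510 (-2.56), AT2G39920 (-2.14), AT3G42800 (-2.09) and AT5G19120 (-2.04) completed the 15 largest falls. The limma adjusted p of these 15 genes ranged from 0.0173 to 0.0496. AT3G42800, dim in 1 dexamethasone array, had 0.0533 and 0.0732 in limma without untreated replicate 1 and 2.

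**Figure D2:**
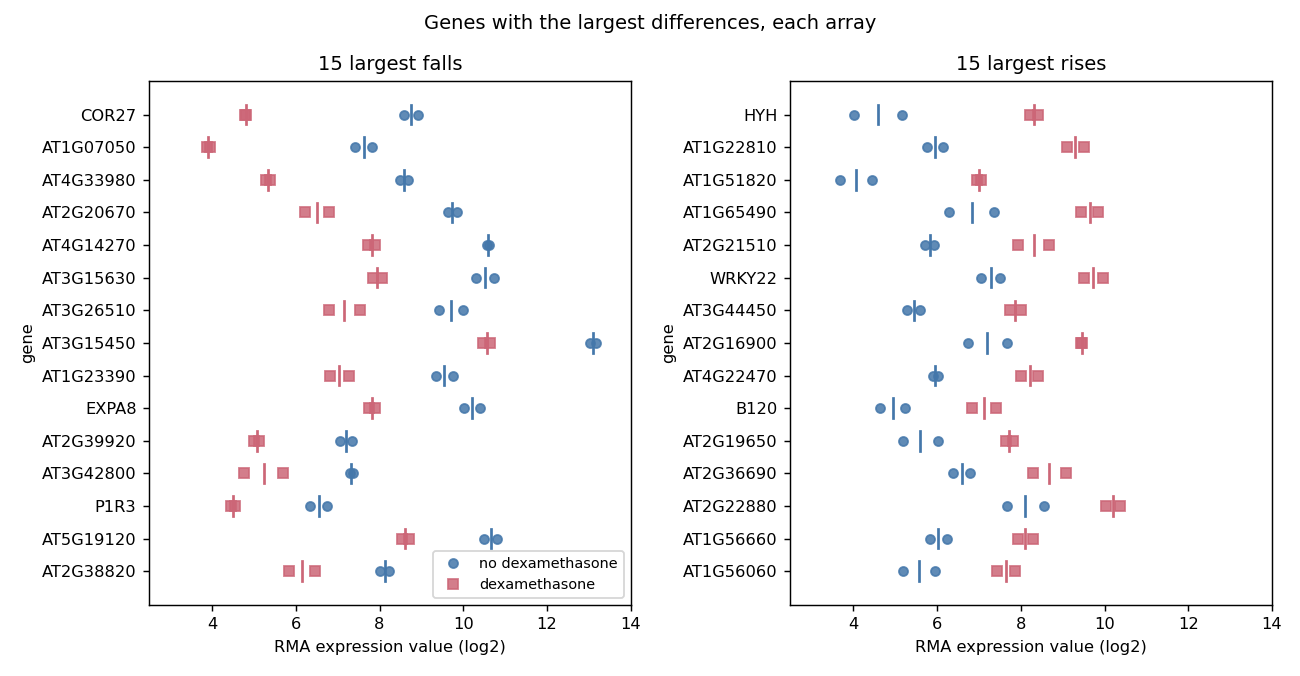
RMA expression values (log2, horizontal axis) of the 15 genes with the largest falls (left) and the 15 with the largest rises (right), with circles for the 2 untreated arrays, squares for the 2 dexamethasone arrays and a vertical bar at each group mean. In each gene the squares and circles do not overlap, because the rule that chose the genes required this. The means run from 8.75 and 4.81 for COR27 to 5.57 and 7.64 for AT1G56060.

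The lists fixed for seed development had few measured members, and none of those was called. A list gene counts as measured here where a probe set was matched to it alone. As 8730 of the 22746 tested probe sets were matched to no gene here, the other members were left unidentified. LEC1, NF-YB6, LEC2, FUS3 and ABI3 were not analysed here. Of the seed maturation regulators, 2 of 15 were measured, with differences of -0.04 for BBM and -0.04 for EEL. Of the storage protein and oil body genes, 2 of 15 were measured, with 0.02 for AT3G01570 and -0.01 for PAP85. Of the fatty acid and oil genes, 2 of 19 were measured, with -0.42 ± 0.19 for the thioesterase gene FATB (-0.24 without untreated replicate 2 and -0.25 without dexamethasone replicate 2) and -0.09 for FaTA. COR15A, a late embryogenesis abundant type protein gene of cold response, stood at 9.31 and 5.15 in the untreated arrays, and its difference of 1.58 ± 1.36 did not pass the limma test. That sign rested on untreated replicate 2, without which the difference was -0.50, while without untreated replicate 1 it was 3.66. No NF-Y subunit of the list was identified.

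Of the 17 auxin genes fixed beforehand, 7 were measured and 1, IAA29, fell (-1.78 ± 0.15, limma adjusted p = 0.0231). The differences were -0.73 for GH3.3 and -0.67 for GH3.5 (-0.34 without untreated replicate 2), neither past the test, and 0.18 for YUC4. The list's mean was -0.50 and its median -0.35 (camera, adjusted p = 0.0428, Benjamini-Hochberg over the 2 lists tested). With an estimated correlation camera's adjusted p was 0.283. That setting tests on few residual degrees of freedom, so it cannot tell whether the shift depends on correlation between genes. Camera's adjusted p was 0.197 without untreated replicate 2 and 0.095 without dexamethasone replicate 1. Without the dimmest 50% of probe sets the mean of the 4 auxin genes left was -0.88. Adjusted over the list alone, 1 gene was called. The 7 measured genes that share the symbol IAA, IAA29 among them, had a mean of -0.28 but a median of 0.04. They did not pass as a family (camera, Benjamini-Hochberg adjusted p = 0.641). Of the gibberellin list 2 of 14 genes were measured, GID1A at -1.54 ± 0.18 (limma adjusted p = 0.0342) and GID1B at 1.19 ± 0.17 (limma adjusted p = 0.045), and both were also called adjusted over the list alone. GID1B lost its call without untreated replicate 2 (1.04, limma adjusted p = 0.0686). Of the brassinosteroid and elongation list only EXPA8 was measured, which was called on both counts.

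Other lists had measured members but no call, over all probe sets or adjusted over the list alone. GI, the clock gene, stood at -0.29 ± 0.13, and the type-A response regulator genes RR16 and ARR15 at 0.10 and -0.04. PORB, of chlorophyll synthesis, stood at -0.85 ± 0.28, and at -0.55 without dexamethasone replicate 2, while LHCB4.1, of the light-harvesting antenna, stood at 0.03. DFR, of anthocyanin synthesis, stood at 0.14. The stem cell gene CLV3 and the leaf polarity gene YAB3 stood at -0.12 and -0.07. The touch and wound genes WRKY53 and STZ stood at 0.59 ± 0.20 and 0.99 ± 0.59. STZ was 0.09 without untreated replicate 2 and 1.89 without untreated replicate 1, and WRKY53 was 0.37 and 0.80. In the stomatal and trichome list, 4 of 12 genes were measured, with 0.29 for TRY and -0.31 for FMA (FAMA), which was -0.14 without untreated replicate 1 and -0.47 without untreated replicate 2, and the mean was 0.04 (camera, Benjamini-Hochberg adjusted p = 0.782). RR16, DFR, TRY, BBM and PAP85 lay at or below the control level in all 4 arrays, so their differences carry little information. CLV3 lay there in 1 untreated and 2 dexamethasone arrays. The jasmonate, heat shock, cell cycle, epidermis and vascular lists had no measured member.

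Of the families tested by shared symbols, a choice made after the annotation was seen, WRKY passed camera with a positive mean and EXPA and ATG with a negative one (Benjamini-Hochberg adjusted p = 0.0357 each), though most members of each were uncalled. Each had adjusted p = 0.885 in camera with an estimated correlation, a value that most of the tested families shared. As for the auxin list, that setting tests on few residual degrees of freedom. It therefore cannot tell whether the shifts of these families depend on correlation between genes. WRKY22 and WRKY6 (1.69 ± 0.13) were the 2 called members of 6 WRKY genes, whose mean was 0.79 and whose median was 0.32, and the 4 uncalled members had a mean of 0.14 and a median of 0.05. EXPA8 was the 1 called member of 10 alpha-expansin genes, whose mean was -0.66, or -0.47 for the 9 uncalled members. Root genes lay lower beside them, with a median of -0.43 for 8 root genes (95% of random lists between -0.15 and 0.15), EXPA7 and EXPA18 among them, in a list written after the calls were seen. Of the 8, AGL21 and AGL42 lay at or below the control level in all 4 arrays, and the other 6 had a median of -0.60 (random range -0.23 to 0.22). Without untreated replicate 2 the medians were 0.11 for the 8 and 0.24 for those 6. ATG8E, of autophagy (-1.26 ± 0.13), was the 1 called member of 8 ATG genes, whose mean was -0.40, or -0.28 for the 7 uncalled members. Without the dimmest 30% or 50% of probe sets all 8 ATG genes and their mean of -0.40 were kept, and the adjusted p was 0.134 in both. The adjusted p rose to 0.19 for EXPA and to 0.16 for WRKY and ATG without untreated replicate 2. It was 0.0731, 0.262 and 0.0807 for EXPA, WRKY and ATG without dexamethasone replicate 1, and 0.0924 for EXPA without dexamethasone replicate 2. The root hair expansins EXPA7 and EXPA18 stood at -0.86 ± 0.42 and -0.57 ± 0.52, uncalled, and at -0.25 and 0.23 without untreated replicate 2. EXPA7, the 1 measured gene of the fixed root list, read 5.03 and 6.25 in the untreated arrays against 4.59 and 4.97 with dexamethasone, and without untreated replicate 1 the differences of EXPA7 and EXPA18 were -1.47 and -1.37.

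**Figure D3:**
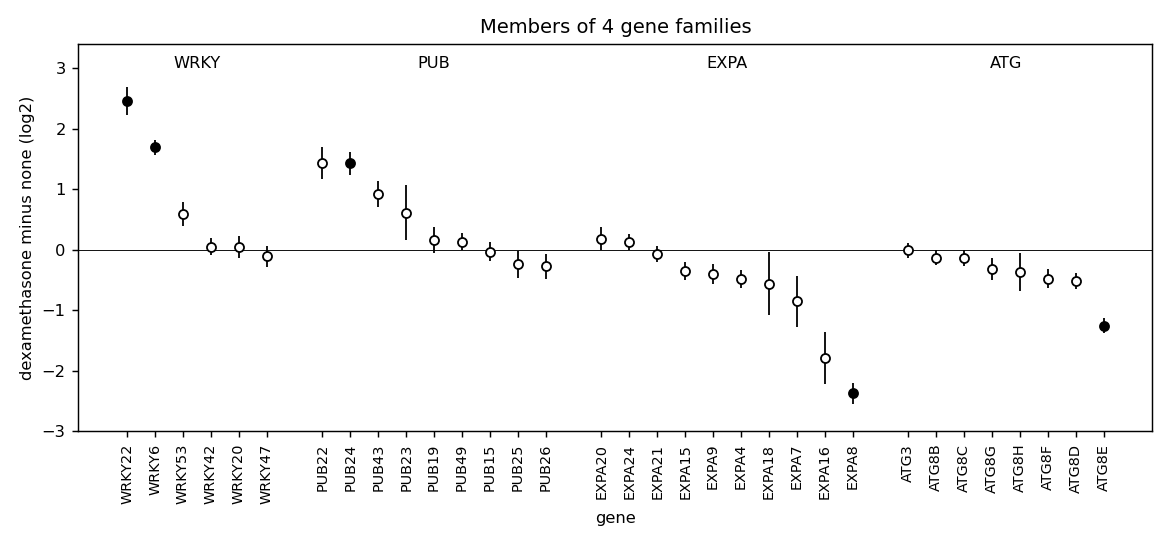
Log2 difference (dexamethasone minus none, vertical axis, with limma's standard error as bars) of each measured gene of the WRKY, PUB, EXPA and ATG families, with filled symbols for called genes. WRKY22 and WRKY6 stand above the other WRKY genes, PUB24 is the filled PUB gene at 1.42, and EXPA8 and ATG8E are the filled genes below 0.

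The counts depended on single arrays, and the spread of the groups was unequal. The SD of the difference between the 2 arrays was 0.41 in the untreated group and 0.28 in the dexamethasone group. The main fit pools both spreads. A fit without 1 array takes its spread from the pair left whole. Without dexamethasone replicate 1 or without dexamethasone replicate 2, limma called 0 probe sets, with 2672 and 2448 at an unadjusted p below 0.05. Without untreated replicate 1 it called 734 higher and 458 lower, and without untreated replicate 2 it called 243 and 189, of which 300 were among the 539. No dexamethasone-treated plants without the fusion were among the samples, so effects of dexamethasone alone were not separated from those of LEC1-GR.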

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

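The settings here were planned before the data were examined, except those of the symbol families and the floor at the control level. The 33 called genes the rule chose kept direction in every alternative, and 10 of the 20 uncalled changed it in at least 1. Of the other named genes, run later, the 18 called kept direction and 6 of 17 uncalled changed it somewhere. None of the 539 calls changed sign. Leaving out 1 array cannot reverse calls whose groups do not overlap, and otherwise only the 2 scalings could. Dim probe sets left out, 2 further scalings, trend or robust eBayes and a 2-fold minimum gave counts within 1.5 times of 339 and 200. With the replicate number as a block, limma called 559 higher and 300 lower, 532 of them among the 539, and camera's adjusted p of the auxin list (-0.50) was 0.0543. Among all these genes the block ended no call and added 2, PORB (-0.85, limma adjusted p = 0.0466 against 0.218 without the block) and PUB22 (1.43, 0.0278 against 0.0708). With a trend FHL and SMZ lost theirs (0.0585 and 0.0525). The replicate deviations of the groups correlated at 0.227, from only 2 pairs, so the numbers were not treated as pairs. The unmoderated test called 0 and 0 (2580 at an unadjusted p below 0.05), as it has few degrees of freedom, and an adjusted p of 0.01 called 0 and 0 in limma (3902). Fewer probe sets entered when only those that match 1 gene were tested (172 and 101). Leaving out 1 array gave 0 to 734 higher and 0 to 458 lower probe sets, and the lone array was then assumed to vary like the other group. Without either dexamethasone array the spread came from the untreated pair alone. That pair lay further apart than the dexamethasone pair (SD of the difference 0.41 against 0.28). Whether this alone ended the calls was not tested. The simulation given next cannot tell, because it drew an equal spread for both groups. A simulation with 2000 changed probe sets called 1902 with 4 arrays and 1650 with 3. The auxin mean ranged from -0.62 to -0.39 and the stomatal mean from -0.13 to 0.20 when 1 array was left out. The auxin call ended in camera when the correlation was estimated (-0.50, adjusted p = 0.283), though the estimate of -0.12 lay below the preset 0.01. That setting tests on the few residual degrees of freedom of 4 arrays. The loss of this call is therefore no sign of correlation between the genes. Quantile normalization applied once more gave -0.013 for LHCB4.1 and -0.00025 for AT3G01570. Leaving out 1 array gave -0.15 to 0.069 for ARR15, -0.032 to 0.095 for LHCB4.1, -0.26 to 0.30 for AT3G01570, -0.17 to 0.16 for PAP85 and -0.46 to 0.28 for FaTA. It gave 0.0066 to 0.20 for RR16, 0.062 to 0.22 for DFR, 0.11 to 0.25 for YUC4, -0.50 to 3.66 for COR15A, -0.15 to 0.064 for EEL, -0.23 to 0.15 for BBM, -0.42 to 0.18 for CLV3 and -0.14 to 0.0035 for YAB3. The cause of these changes was not tested. Without the dimmest 30% or 50% of probe sets the ATG call ended (adjusted p = 0.134 in both) at the same mean of -0.40 over the same 8 genes. Sets that lost members had means further from 0, with -0.75 and -0.88 for auxin (5 and 4 genes left), -0.83 and -1.25 for EXPA (8 and 4) and 0.93 and 1.20 for WRKY (5 and 4). The motif test with 500 bp or 1000 bp was not run. Signal near background limits dim genes, as no detection call was used here.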

Other observations

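The genes of this paragraph were chosen after their values were seen, and each passed limma's test with Benjamini-Hochberg adjustment. No list of their functions was fixed or tested, so they stand for single genes and not for pathways. EFR, an immune receptor gene, rose by 1.29 ± 0.15 (log2 difference ± SE), BIK1, a receptor-like kinase gene, by 0.93 ± 0.12, and the ubiquitin ligase genes PUB24 and RING1 by 1.42 ± 0.20 and 2.07 ± 0.29. OPCL1, of jasmonate synthesis, rose by 1.81 ± 0.20. AFR and FHL, named in phytochrome signalling, rose by 1.74 ± 0.24 and 0.90 ± 0.12, and SHB1 by 1.98 ± 0.18, at least 3.4-fold because both untreated arrays lay at or below the control level. UGT78D2, a flavonoid glucosyltransferase gene, rose by 1.503 ± 0.22, AT5G15950 by 1.89 ± 0.18 and SMZ, a floral repressor, by 1.03 ± 0.15. PWD and DPE1, which act in starch breakdown, fell by 1.32 ± 0.18 and by 1.16 ± 0.12. AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, fell by 1.60 ± 0.20, and AT4G33150, of lysine breakdown, fell by 0.93 ± 0.12. THIC, of thiamine synthesis, fell by 1.78 ± 0.14. Without untreated replicate 2, the calls of PUB24, RING1, BIK1, AFR, FHL, SMZ, PWD, AKINBETA1 and AT4G33150 ended in limma, with adjusted p from 0.0528 to 0.0734, and FHL also lost its call without untreated replicate 1 (0.0534). Without either dexamethasone array none of them was called.

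The untreated arrays differed at least 4-fold in 118 probe sets, 33 higher in replicate 1 and 85 in replicate 2, against 3 for the dexamethasone arrays. COR15A and COR15B, of cold response, read 9.31 and 10.91 in untreated replicate 1 against 5.15 and 7.75 in replicate 2. The peroxidase genes AT4G30170, AT4G26010 and AT3G49960 read 10.08, 9.19 and 8.37 in replicate 2 against 6.67, 5.90 and 5.23 in replicate 1. The control probe set for large-subunit ribosomal RNA read 8.22 and 8.96 in the untreated and dexamethasone arrays numbered 1, and 10.96 and 10.48 in those numbered 2.

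The tests below on root genes, on calls without untreated replicate 2, on GI and on splits of the arrays were chosen after the results they bear on had been seen. The carbon-starvation, wound, RNA end and neighbour tests were written before their values were seen, though after the calls. The first of 3 patterns is the set of 539 calls together with the distance of untreated replicate 2. The hypothesis of root tissue in that array was put to 8 root genes, whose median was 1.41 higher there than in untreated replicate 1 (7 of 8 higher, 95% of random lists between -0.17 and 0.22). Without EXPA7 and EXPA18, whose values were known when the list was written, the median of the other 6 was 1.19, PYK10 read 12.28 against 11.57, and AGL21 and AGL42 lay at or below the control level throughout (median of the 8 without these 2, 1.63). The 8 genes were also higher in dexamethasone replicate 2 than in replicate 1 (median 0.23, 6 of 8, random range -0.15 to 0.19). They were lower with dexamethasone (median -0.43, or -0.25 for the 6, but 0.11 for the 8 without untreated replicate 2). Root tissue may therefore differ between arrays. Without untreated replicate 2 limma called 432 probe sets, of which 300 were among the 539. Root tissue in that array alone could thus not be the whole source of the calls. Whether root tissue was behind the calls that ended, or differed between the other arrays, stays open. Unequal RNA degradation of the size predicted was not seen in the 3 control genes. Their 3' minus 5' values differed by 0.0464 on average and went both ways (actin 0.218, GAPDH 0.110, ubiquitin -0.189). Each of these differences lay under the bound set beforehand for their mean, so no large difference was seen in these genes. The groups did not overlap for actin (2.68 and 2.37 untreated, 2.71 and 2.77 with dexamethasone). Nor did they for ubiquitin (1.55 and 1.43 untreated, 1.29 and 1.31 with dexamethasone). As these 2 genes went in opposite directions, the test was undecided, and a smaller difference in degradation stays open. Of the 3 splits of the arrays into pairs 1 called as many, the others calling at most 0 in limma (735 and 165 at an unadjusted p below 0.05), with 3 splits too few to judge chance.

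The second pattern is the fall of AT3G15450, AKINBETA1 and ATG8E. If carbon supply differed between the arms, uncalled carbon-starvation genes should fall too. The 14 tested had a median of -0.38 (14 of 14 lower, 0 called in limma, 95% of random lists between -0.25 and 0.14), but 6 of them belong to the ATG family already given, and the other 8, with MCCA at -0.74 and ETFQO at -0.60, had a median of -0.50 (random range -0.30 to 0.23). Without untreated replicate 2 the median was -0.26, inside that setting's random range of -0.28 to 0.15, and that of the 8 was -0.41, outside its range of -0.34 to 0.25. A difference in carbon status is therefore a candidate explanation that rests in part on 1 array, the protocol names the same sucrose medium for both arms, and an action of LEC1-GR on these genes stays open and untested.

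The third pattern is the rise of WRKY22, WRKY6, PUB24, RING1 and OPCL1. If the dexamethasone arm had been touched or wounded more, uncalled wound and touch genes should rise too. The 10 tested had a median of 0.80 (9 of 10 higher, 0 called in limma, 95% of random lists between -0.25 and 0.19), with PUB22 at 1.43, CML42 at 1.40 and ORA47 at -0.82, and the 6 outside the WRKY and PUB families and the fixed touch list had a median of 0.75 (random range -0.29 to 0.26). In replicate 2 minus replicate 1, those 6 had medians of -0.87 in the untreated arrays (random range -0.29 to 0.26) and -0.41 in the dexamethasone arrays (-0.22 to 0.23). These genes thus left the random range between arrays of the same treatment too, so that range does not cover the variation between arrays. Without untreated replicate 2 the median of the 10 was 0.22, against a random range of -0.27 to 0.21, and that of the 6 was 0.20, inside its range of -0.31 to 0.29, so much of the rise came from low values in that array. CML42 was 1.74 without untreated replicate 2 and 1.07 without untreated replicate 1, and ORA47 was -1.58 and -0.05. Handling may have differed, but these genes also respond to immune signals, WRKY53 and STZ belong to the fixed touch list as well, and neither dexamethasone itself nor LEC1-GR was excluded.

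Other tests are given as values. GI, tested for a different time of harvest beside the fall of COR27, AT4G33980 and AT1G07050, differed by -0.288 (95% interval -0.62 to 0.04), which left the question undecided. A first form of that test also held CCR2 and gave a median of 0.29. CCR2 was dropped after its value was seen, because the symbol stands here for a cinnamoyl-CoA reductase gene and not for the clock-regulated RNA-binding protein. Over 5814 pairs of adjacent measured genes the differences correlated at 0.0711 across genes, which are not independent replicates (permutation p = 0.0001, the smallest that 10000 shuffles can give). In 4 pairs both genes were called, against 2.20 by chance (permutation p = 0.177), and 3 of these pairs moved in opposite directions. The symbol families PUB (mean 0.46) and TUB (mean -0.40) and the 69 plastid-genome genes (median -0.21) did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.129, 0.121 and 0.129).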
